A study of Mus musculus with 4 samples.

How the data were processed

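Single-cell RNA sequencing was run on cells from transplanted mouse hearts collected 5 days after transplantation. Per the labels, 3 libraries came from allogeneic grafts (replicates 1, 2 and 3) and 1 from an isogeneic graft (replicate 2), that is, from a donor genetically identical to the recipient. Grafts were digested with enzymes, per the series' design text, and libraries were made with the Chromium Next GEM Single Cell 3' kit v3.1, per the labels' protocols. The labels name no mouse strain, no cell sort and no treatment aimed at VISTA, and nothing in them says whether the replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

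The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized, for 34097 genes per library. The submitters' processing notes name Cell Ranger 3.1.0 and the genome build mm10, while the matrix headers, written by the authors' pipeline, name version 6.1.0; which of them made the counts is not given in the sources used here. Whether the counting used strand is likewise not given. Of the gene identifiers, 32403 were found in the GENCODE M21 annotation of that build, 29819 of them with the same symbol, and 38 symbols were carried by more than 1 identifier. Total counts per library were 51054446, 63434265 and 51463909 UMIs over 6160, 8396 and 6554 barcodes for allogeneic replicates 1, 2 and 3, and 100038951 UMIs over 11473 barcodes for the isogeneic library.

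Barcodes with under 500 UMIs or under 300 genes were left out (1101, 91 and 146 in the allogeneic libraries and 44 in the isogeneic one), as were those with over 20% of UMIs from mitochondrial genes (76, 90, 97 and 43). Scrublet scored doublets in each library, and the highest scores were removed at a rate of 0.8% per 1000 barcodes, fixed before the data were examined, which took 246, 552, 331 and 1045 cells. Its automatic threshold, not used, would have marked 1, 0 and 3 cells in the allogeneic libraries and 1332 in the isogeneic one. The 28721 cells kept numbered 4737, 7663, 5980 and 10341, with median UMIs of 7502, 5793, 5194.5 and 5996. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and Leiden clustering on 15 nearest neighbours at resolution 1 gave 27 clusters (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Libraries were not integrated, since library and group cannot be separated in the isogeneic arm. The weights of the neighbour graph were corrected once after results of earlier clusterings had been seen, because rounding had left cells at a distance just above 0 from themselves. Every value given comes from the corrected graph.

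Clusters were named from marker lists fixed before the data were examined, as the class whose markers had the highest mean z score across clusters. The scoring rule itself was written afterwards. A name ending in "like" is understood for each class throughout (macrophage-like, shortened to macrophage). A marker counted as detected when found in at least 10% of a cluster's cells at 1.5 times its level elsewhere, and clusters with under 3 detected markers, with more markers of another class among their 10 leading genes, or with few UMIs and no marker of their own among those genes stayed unnamed. The leading genes of a cluster are not given as results. Macrophages came mostly from cluster 2 and the dividing cluster 24 in the isograft and mostly from cluster 10 in the allografts. Endothelial cells came mostly from cluster 7 in the isograft and 3 in the allografts, and neutrophils from 20 and 16. Dendritic cells of both groups came from cluster 18 and mural cells from cluster 15.

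Raw counts were summed per library and class, and allogeneic was compared with isogeneic by the edgeR 4.0.16 quasi-likelihood F-test (TMM scaling, default expression filter, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05) where each library held at least 20 cells of the class. The lone isogeneic library is assumed to vary like the allogeneic ones, which leaves 2 residual degrees of freedom. Each SE given is the absolute log2 change divided by the square root of the F statistic. It was not estimated directly and is only approximate, above all for large changes. CPM values, computed here from the deposited counts, are a gene's counts relative to all UMIs of the class in a library, with the SD over the 3 allogeneic libraries. Fixed gene lists, 31 in all, were tested with camera (limma 3.58.1, R 4.3.3) at a preset correlation of 0.01 and again with the correlation estimated from the libraries; lists with at least 3 tested genes entered. Shares of cells were compared with edgeR on cell numbers and with an exact permutation test. For comparisons within a library (Vsir between classes, macrophages with and without a Vsir UMI, and the difference of the allogeneic effect between classes) the library was a block. Before macrophages were divided by a Vsir UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. A fold against an isogeneic sum of 0 is a lower bound computed against 3 counts in that sum; where the isogeneic sum held 1 to 3 counts, the ratio of pooled counts is given with a 95% exact interval. Intervals cover counting error only.

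Named genes followed a rule fixed before the data were examined. For macrophages it took Vsir and 12 further genes (H2-Ab1, Ciita, H2-K1, Cxcl9, Cxcl10, Il1b, Tnf, Nos2, Arg1, Cd274, Cd80 and Cd86), the 2 members of each list past the threshold with the largest change, and the 5 largest rises and 5 largest falls among genes with at least 50 CPM whose 3 allogeneic libraries lay on the same side of the isogeneic one. For other classes it took Vsir, the 2 largest rises and 2 largest falls, and list members in the same way. Predicted, ribosomal protein and mitochondrial genes were passed over.

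The tests were run on simulated counts with known changes. Every gene was drawn at the common dispersion of the real fit, around a mean shared by all libraries before the changes. No simulated library stood apart from the others, unlike in the real data, so the rates below hold for that setting only. In macrophages (11758 genes) 16.7%, 88.5% and 95.1% of genes changed 2-, 4- and 8-fold were called. In endothelial cells (12957 genes) the shares were 1.56%, 53.1% and 98.4%, and in T cells (13431 genes) 0%, 1.69% and 16.1%. For macrophages divided by a Vsir UMI (4867 genes), 51.5%, 91.9% and 100% of changes of 1.5-, 2- and 4-fold were called. False calls were 12 of 134 in macrophages, 6 of 102 in endothelial cells, 0 of 10 in T cells and 9 of 162 in macrophages divided by a Vsir UMI.

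Alternatives fixed before the data were examined were DESeq2 1.42.0, other scaling, no expression filter, doublets kept, a mitochondrial limit of 10%, resolutions 0.5 and 2, macrophages joined with monocytes, equal numbers of thinned macrophages, other thinning depths, cells matched by cluster, no library block and leaving out each library. Added after seeing the data were clustering seeds 2 to 6, macrophages without the dividing cluster, T cells without a mixed cluster, library size scaling in endothelial cells, monocytes and T cells scaled to a median log2 change of 0 over all genes, and a set of fibroblast cells joined with the unnamed clusters that scored highest for fibroblast markers. The planned comparisons in NK cells and fibroblasts, and the planned difference between macrophages and fibroblasts, were not run, because 1 library held 10 NK cells and another 1 fibroblast. Mural cells were numerous enough in each library, but no allogeneic comparison of their genes was planned or run.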

Results

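Cells of transplanted mouse hearts were profiled by droplet single-cell RNA sequencing on day 5 after grafting, in 3 allogeneic libraries, from hearts placed into genetically different recipients, and 1 isogeneic library (the isograft). Sequencing gave 51054446, 63434265 and 51463909 UMIs in allogeneic replicates 1, 2 and 3 and 100038951 in the isograft, and 4737, 7663, 5980 and 10341 cells were kept. The allogeneic libraries differed from each other by more than sampling noise, with a chi-square per gene of 18.2 between replicates 1 and 2, 358 between 1 and 3 and 380 between 2 and 3. Against the isograft it was 980, 1065 and 480. This measure grows with sequencing depth, which was greatest in the isograft, and takes in differences in cell composition. Its values are therefore not distances on a common scale. Replicate 3 thus stood apart from the other allografts, and values are given per library where it differed most. Each change called below with all 4 libraries in the fit lay on the same side of the isograft in all 3 allogeneic libraries.

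The first question was which cells the grafts held. T cells made up 18.5% ± 10.4 of allograft cells (SD, n = 3) and 0.416% of isograft cells (Wilson 95% interval 0.309 to 0.560), and NK cells 2.82% ± 0.226 and 0.0967% (0.0525 to 0.178). Macrophages and monocytes together made up 33.2% ± 8.81 of allograft and 28.7% of isograft cells. Within that joint share, monocytes were 28.0% ± 7.73 in the allografts and 0.309% in the isograft, and macrophages 5.15% ± 1.21 and 28.4%. The border between the pair rests on clusters whose leading genes differ between the groups, as monocytes fell mainly in cluster 0 in replicates 1 and 2 and in cluster 9 in replicate 3 and the isograft. With another clustering seed the macrophage share of replicate 1 was 26.4% in place of 6.27%. With edgeR on cell numbers over 12 classes, the shares of NK cells (log2 change 4.84, SE 0.79) and monocytes (6.49, SE 1.00) rose, each with an edgeR adjusted p = 0.0225. T cells (5.47, SE 1.41, edgeR adjusted p = 0.0549) and macrophages (-2.46, SE 0.58, edgeR adjusted p = 0.0535) did not pass. The T cell share was 25.8%, 23.1% and 6.62% in replicates 1, 2 and 3, and without a cluster that also carried heart muscle and immunoglobulin transcripts it was 13.9% ± 6.37.

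Fibroblasts, the matrix-producing cells of the heart, were 2.72% ± 4.61 of allograft cells and 44.1% of isograft cells (43.2 to 45.1). With unnamed clusters that scored highest for fibroblast markers added, the shares were 1.63%, 1.88% and 26.3% in replicates 1, 2 and 3 and 48.8% in the isograft. The fibroblast share itself did not pass (-4.02, SE 2.83, edgeR adjusted p = 0.344). Endothelial cells were 10.5% ± 2.55 and 10.6% (edgeR adjusted p = 0.975), neutrophils 3.49% ± 3.28 and 3.98% (0.962) and conventional dendritic cells 2.21% ± 0.901 and 1.62% (0.715). Mural cells (1.22% ± 0.434 and 4.42%) and cardiomyocytes (1.59% ± 1.32 and 0.0387%) each had an edgeR adjusted p = 0.113, and lymphatic endothelial cells (0.328% ± 0.248 and 0.619%) one of 0.713. Unnamed clusters held 23.5% ± 9.53 and 5.36% (0.113). An exact two-sided permutation test gave p = 0.25 for NK cells, monocytes, macrophages, T cells, mural cells and fibroblasts, the smallest that 4 libraries allow. Without replicate 1 or without replicate 2 the number of classes passing fell from 2 to 0, and without replicate 3 it was 9.

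**Figure D1:**
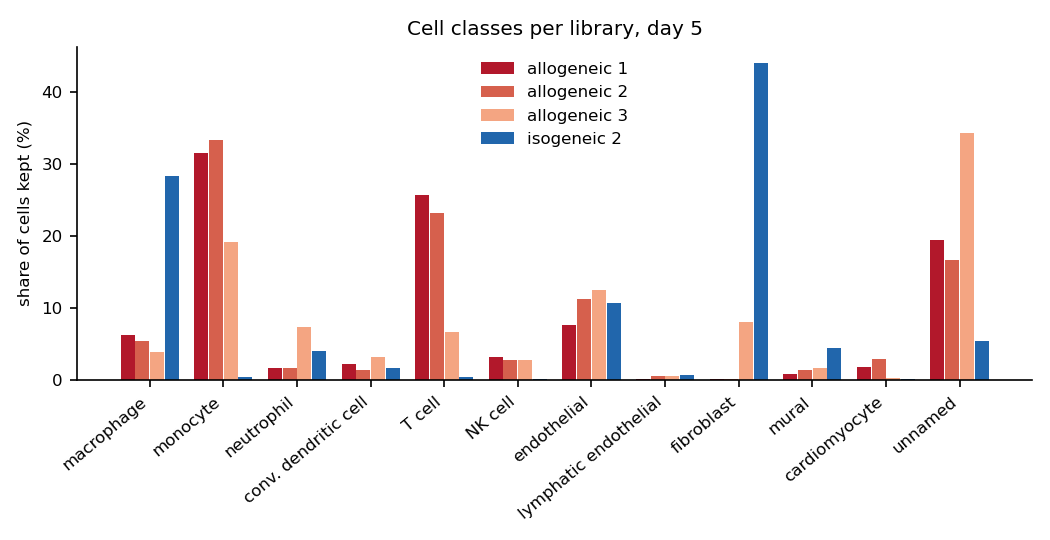
Each bar is the share of kept cells, in percent, that 1 library held in a class, with the 3 allogeneic libraries in reds and the isograft in blue. T cells were at 25.8%, 23.1% and 6.62% in the allografts and 0.416% in the isograft.

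The main comparison asked how macrophages differ between grafts under alloimmune attack and isografts, and what becomes of Vsir, the gene of the inhibitory receptor VISTA, which the study places in macrophages as a brake on inflammatory and antigen-presenting programs. Vsir was read at 107 ± 35.9 CPM in allograft macrophages (SD, n = 3) and 109 CPM in the isograft, a log2 difference of -0.0034 (SE 0.36, edgeR adjusted p = 0.996). Per library it was 131, 125 and 65.8 CPM in replicates 1, 2 and 3, and without replicate 3 the log2 difference was 0.23. The chemokine Cxcl9, which draws activated T cells, rose to 4051 ± 1727 CPM from 1.68 (log2 11.25, SE 0.83, edgeR adjusted p = 0.00256). Nos2, the inducible nitric oxide synthase, rose to 83.9 ± 29.2 CPM from 0.249 on 4 isograft counts (8.31, SE 0.64, edgeR adjusted p = 0.00303). Ciita, the master regulator of MHC class II, rose to 112 ± 36.0 CPM from 4.73 (4.59, SE 0.47, edgeR adjusted p = 0.00632). In all, 747 of 12071 genes passed the edgeR test, 466 higher and 281 lower. The share of rises, 62.38%, was 47.35% without replicate 3 and 49.14% with no filter, and lay between 50.02% and 89.74% in the other settings. Most isograft macrophages came from cluster 2 and most allograft macrophages from cluster 10. The count was 503 without replicate 1, 117 without replicate 2 and 4788 without replicate 3. With 5 other clustering seeds, tried after the data were seen, it was 1168 to 2071, and with resolution 2 it was 271. Macrophages of replicate 1 numbered 297 to 1251 over seeds.

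Vsir (ENSMUSG00000020101) lies on chromosome 10 from 60346851 to 60372684 on the plus strand of mm10, within the span of Cdh23 (60302748 to 60696490) on the opposite strand. Since strand use in the counting is not given, reads from Cdh23 cannot be excluded. The list of VISTA and its reported binding partners had 3 of 5 members measured and none passed, also adjusted over the list alone; its median was -0.0034 while its mean and test pointed up (camera adjusted p = 0.91, and adjusted p = 0.95 with an estimated correlation).

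Antigen presentation genes were higher as groups. Of 12 class II genes 11 rose (12 adjusted over the list alone), with a median log2 change of 3.24 (camera adjusted p = 1.18e-20, and adjusted p = 0.363 with an estimated correlation). H2-Ab1, a class II chain, stood at 4066 ± 1174 CPM and 279 in the isograft (3.88, SE 0.42, edgeR adjusted p = 0.00679), and H2-Eb1 rose by 4.16 (SE 0.64). Of 20 class I genes 17 rose (19 adjusted over the list alone, median 2.25, camera adjusted p = 1.09e-27, and adjusted p = 0.129 with an estimated correlation), among them H2-K1 at 3996 ± 297 CPM against 1047 (1.95, SE 0.22, edgeR adjusted p = 0.0082), the peptide transporter Tap1 (3.48, SE 0.32) and Tapbpl (3.26, SE 0.28). Of 12 co-stimulatory ligands, Slamf7 (3.88) and Cd40 (2.64) rose, 1 fell and 9 did not pass (4 up and 2 down adjusted over the list alone, median -0.55, camera adjusted p = 0.91, and adjusted p = 0.95 with an estimated correlation). Cd86 was at 343 ± 29.5 CPM and 198 (0.82, SE 0.22, edgeR adjusted p = 0.0829) and Cd80 at 8.41 ± 0.866 and 10.6 (-0.33, SE 0.29, edgeR adjusted p = 0.554). The direction of Cd80 was unstable: it stayed negative over left-out replicates but turned positive in other settings, such as doublets kept (0.14) and monocytes joined (0.96).

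Of interferon-gamma response genes, 26 of 28 rose (27 adjusted over the list alone), with a median of 4.13 (camera adjusted p = 3.18e-84, and adjusted p = 0.129 with an estimated correlation). Tgtp1, which shares reads with its copy Tgtp2, was at least 76.6-fold higher. Type I interferon response genes numbered 11 rises of 30 (16 adjusted over the list alone, median 1.30, camera adjusted p = 2.07e-10, and adjusted p = 0.412 with an estimated correlation), with the nucleic acid sensor Zbp1 (3.03, SE 0.28) and Irf7 (2.54, SE 0.36). The largest single rises were Cxcl9, Ubd (at least 574-fold), Gbp8 (9.09, on 7 isograft counts), Serpina3g (8.38, on 11) and Ly6i (pooled ratio 1039, interval 287 to 8592, on 2 counts), whose family shares sequence. Falls were ranked among genes with at least 50 CPM. The largest included the fractalkine receptor Cx3cr1 (-2.92, SE 0.62), Phlda1 (-2.67, SE 0.43), Fabp4 (-2.54, SE 0.21) and Gdf15 (-2.48, SE 0.23). Cx3cr1 was a marker used to name macrophage clusters and Fabp4 one used to name endothelial clusters. Their changes cannot be told apart from which clusters got which name. Of 55 named genes that passed, 31 lost their call without replicate 2, with log2 changes 0.889 to 1.15 times those with all libraries, and 5 lost it without replicate 1.

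Inflammatory genes were mixed in direction. Of 19 mediators 6 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.78, camera adjusted p = 3.72e-05, and adjusted p = 0.322 with an estimated correlation), and those that rose included Nos2 and the acute-phase gene Saa3 (4.25, SE 0.71). The cytokines Il1b (112 ± 32.1 CPM and 217; -0.93, SE 0.30, edgeR adjusted p = 0.129) and Tnf (187 ± 120 and 390.1; -1.03, SE 0.57, edgeR adjusted p = 0.332) did not pass. Without replicate 3 Il1b passed as lower (-0.76, edgeR adjusted p = 2.94e-06), and joining monocytes turned it to 2.19 (edgeR adjusted p = 0.151). Il1b was also positive with doublets kept (0.51), at a mitochondrial limit of 10% (0.76), at resolution 2 (0.30) and with seeds 2 to 4. Of 16 NF-kB feedback genes 4 rose (7 up and 3 down adjusted over the list alone, median 0.50, camera adjusted p = 0.0483, and adjusted p = 0.412 with an estimated correlation), with Sod2 (1.94) and Tnfaip2 (1.79); without replicate 3 the camera adjusted p was 0.12. Of 20 chemokines 4 rose and 3 fell (5 and 6 adjusted over the list alone). Their median was -0.57 while their mean was 0.22 and the test pointed up (camera adjusted p = 0.761, and adjusted p = 0.95 with an estimated correlation). Cxcl11 rose to 615 ± 319 CPM from 11.8 (5.74, SE 0.74, edgeR adjusted p = 0.012), whereas Cxcl10 read 454, 419 and 1728 CPM against 576 (0.62, SE 0.84, edgeR adjusted p = 0.714). Without replicate 3 Cxcl10 passed as lower (-0.40, edgeR adjusted p = 0.023). Arg1, of arginine metabolism, was at 177 ± 26.1 and 122 CPM (0.56, SE 0.23, edgeR adjusted p = 0.203).

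Inhibitory molecules of myeloid cells had 5 rises of 17 (6 up and 4 down adjusted over the list alone, median 0.56, camera adjusted p = 0.0189, and adjusted p = 0.412 with an estimated correlation). Cd274, the gene of PD-L1, rose to 523 ± 92.1 CPM from 32.5 (4.02, SE 0.32, edgeR adjusted p = 0.00303), Pdcd1lg2 by 6.08 (SE 1.1), and Ido1, which degrades tryptophan, was at least 21.4-fold higher. Resident and reparative macrophage genes had 8 falls of 18 (3 up and 12 down adjusted over the list alone, median -2.09, camera adjusted p = 7.45e-08, and adjusted p = 0.412 with an estimated correlation), with Gas6, a bridge to dying cells (-4.06, SE 0.75), and Cbr2 (-2.99, SE 0.58). Of 17 monocyte-derived macrophage genes 3 rose, among them Ly6a (7.44) and Ly6c2 (3.12), and 4 fell (4 and 7 adjusted over the list alone, median -1.02, camera adjusted p = 0.16, and adjusted p = 0.412 with an estimated correlation). Ly6c2 was a monocyte marker in the naming of clusters, and changes in such markers cannot be told apart from that naming. The same limit holds for the resident and reparative list. Leading genes of the macrophage clusters that passed included the naming marker Mrc1 and Selenop, a member of that list. Its falls thus cannot be told apart from which clusters got the macrophage name. Complement genes had 3 rises and 1 fall of 12 (5 and 1 adjusted over the list alone, median 0.65, camera adjusted p = 0.00684, and adjusted p = 0.363 with an estimated correlation), with Cfb (5.48) and C3 (4.64). With monocytes joined the complement median was -0.037 (camera adjusted p = 0.407). Efferocytosis genes had 3 rises and 6 falls of 18 (6 and 8 adjusted over the list alone, median -0.74, camera adjusted p = 0.0799, and adjusted p = 0.412 with an estimated correlation).

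Among metabolic and housekeeping groups, 3 of 21 glycolysis and hypoxia genes rose (7 up and 1 down adjusted over the list alone, median 0.74, camera adjusted p = 0.000699, and adjusted p = 0.63 with an estimated correlation), with hexokinase Hk2 (1.80) and Hif1a (1.79). None of 25 oxidative phosphorylation genes (median 0.22, camera adjusted p = 0.228, and adjusted p = 0.835 with an estimated correlation) or 22 cell cycle genes passed, also adjusted over the list alone. The cell cycle list pointed down (median -0.47, camera adjusted p = 0.0112, and adjusted p = 0.749 with an estimated correlation), and without replicate 2 its camera adjusted p was 0.0544. Lysosome genes had 2 rises and 3 falls of 20 (2 and 4 adjusted over the list alone, median -0.034, camera adjusted p = 0.344, and adjusted p = 0.934 with an estimated correlation), with the protease Ctsl lower (-1.85). Immediate-early and heat shock genes, which also answer to tissue dissociation, had 5 falls of 17 (1 up and 12 down adjusted over the list alone, median -1.01, camera adjusted p = 2.65e-06, and adjusted p = 0.363 with an estimated correlation), among them Ier2 (-1.89) and Fosb (-1.88).

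Transcripts of other cells moved with these groups. T and NK transcripts had 4 rises of 13 (13 adjusted over the list alone, median 4.65, or 4.25 with undetected genes at their bound, camera adjusted p = 3.99e-10, and adjusted p = 0.412 with an estimated correlation). The T cell receptor chain Trbc2 read 26.8, 26.6 and 5.64 CPM in allograft macrophages and 0.685 in the isograft, against 1313, 1267, 1074 and 823 in T cells. Cytotoxic genes had 6 rises and 1 fall of 15 (11 and 1 adjusted over the list alone, median 3.90, camera adjusted p = 3.55e-09, and adjusted p = 0.23 with an estimated correlation), with Gzmb (6.32, on 5 isograft counts) and Klrk1 (5.84, SE 0.37). Klrk1 read 85.7, 66.2 and 94.1 CPM, near the 162, 130 and 76.2 of T cells, while Gzmb read 22.8, 41.5 and 11.3 CPM against 2357, 2281 and 2287 in T cells. T cell activation genes had 2 rises of 14 (8 adjusted over the list alone, median 2.00, camera adjusted p = 0.00197, and adjusted p = 0.412 with an estimated correlation), with Lag3 (2.57) and Entpd1 (1.68). Naive T cell genes had 2 rises and 2 falls of 8 (2 and 3 adjusted over the list alone, median 0.12, camera adjusted p = 0.91, and adjusted p = 0.95 with an estimated correlation). Regulatory T cell genes had none of 7 (3 and 1 adjusted over the list alone, median 1.36, camera adjusted p = 0.228, and adjusted p = 0.481 with an estimated correlation).

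Matrix genes had 2 falls of 21, Tagln (-2.73) and Col4a1 (-1.66), and 5 adjusted over the list alone (median -2.31, camera adjusted p = 8.09e-07, and adjusted p = 0.481 with an estimated correlation). Stromal transcripts had 1 fall of 11, Fabp4, also adjusted over the list alone (median -1.61, camera adjusted p = 0.00851, and adjusted p = 0.363 with an estimated correlation), and the collagen Col1a2 read 4.67, 2.49 and 46.6 CPM against 84.3. Endothelial adhesion genes had 1 rise, Vcam1 (3.63), and 1 fall, Csf1 (-2.51), of 11 (3 and 3 adjusted over the list alone, median 0.31, camera adjusted p = 0.91, and adjusted p = 0.95 with an estimated correlation). Immunoglobulin and B cell transcripts had 1 rise of 4, Igkc (4.24; 2 up and 1 down adjusted over the list alone, median 1.52, camera adjusted p = 0.112, and adjusted p = 0.412 with an estimated correlation). Neutrophil transcripts had 1 fall of 9, S100a9 (-1.61; 1 up and 2 down adjusted over the list alone, median -0.33, camera adjusted p = 0.538, and adjusted p = 0.805 with an estimated correlation). Cardiac transcripts had 1 fall of 15, Fabp3 (-0.99; 1 up and 1 down adjusted over the list alone, median 0.93, camera adjusted p = 0.159, and adjusted p = 0.805 with an estimated correlation). None of 4 haemoglobin transcripts passed, also adjusted over the list alone (median 1.30, camera adjusted p = 0.91, and adjusted p = 0.959 with an estimated correlation), though Hbb-bs read 37.1, 938 and 16.5 CPM against 79.4. This list passed in opposite directions when 1 library was left out, with a median of -1.58 without replicate 2 (camera adjusted p = 0.000248) and 1.77 without replicate 3 (camera adjusted p = 0.00868). In all, 17 of 31 lists passed camera, 12 up and 5 down, and 0 passed with an estimated correlation.

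**Figure D2:**
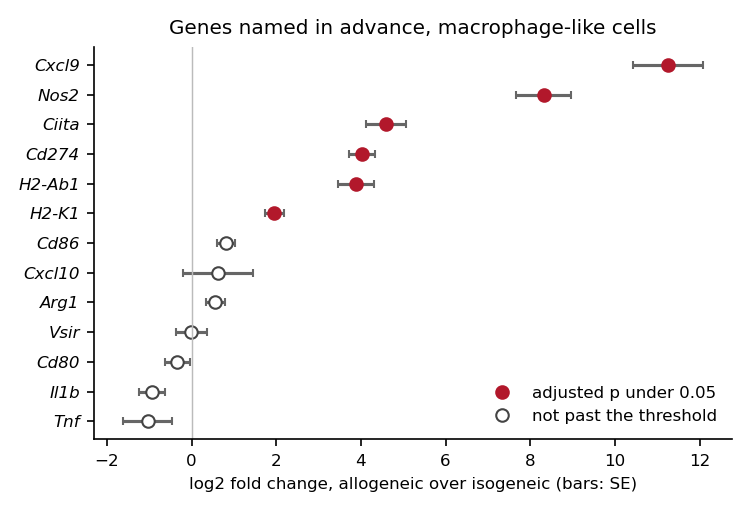
Log2 fold change, allogeneic over isogeneic, of the genes fixed beforehand in macrophages, with bars of 1 SE (approximate, derived from the F statistic) and filled points for an edgeR adjusted p under 0.05. Cxcl9 stood at 11.25 and Vsir at -0.0034.

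The same contrast in endothelial cells asked what the graft's vessel lining carried. Cxcl9 rose there to 7515 ± 2237 CPM from 17.8 (8.78, SE 0.51, edgeR adjusted p = 0.00743), Cd274 to 1178 ± 160 from 33.2 (5.22, SE 0.36, edgeR adjusted p = 0.00937) and the adhesion molecule Vcam1 to 1545 ± 263 from 203 (2.99, SE 0.29, edgeR adjusted p = 0.0171). Ciita rose to 71.2 ± 10.5 CPM from 0.749 on 4 isograft counts (6.59, SE 0.49, edgeR adjusted p = 0.00976). Eln, elastin, fell to 14.7 ± 8.26 CPM from 213 (-3.83, SE 0.44, edgeR adjusted p = 0.0246). Interferon-gamma response genes had 25 rises of 28 (27 adjusted over the list alone, median 4.12, camera adjusted p = 9.3e-109, and adjusted p = 0.068 with an estimated correlation). Type I response genes had 14 of 30 (30 adjusted over the list alone, median 2.64, camera adjusted p = 3.69e-46, and adjusted p = 0.256 with an estimated correlation). Class I genes had 14 of 20 (20 adjusted over the list alone, median 2.35, camera adjusted p = 5.69e-42, and adjusted p = 0.068 with an estimated correlation). Class II genes had 7 of 11 (8 adjusted over the list alone, median 3.94, camera adjusted p = 3.19e-21, and adjusted p = 0.3 with an estimated correlation). H2-Q6 (7.20) and H2-Q7 (6.06), near-identical class I copies whose reads may be split between them, and H2-Eb1 (6.45) rose. With no strain named and mm10 as the only build, strain differences in H2 genes cannot be told from expression changes in any class. Of 21 chemokines 4 rose (7 adjusted over the list alone, median 1.16, camera adjusted p = 1.11e-07, and adjusted p = 0.256 with an estimated correlation), among them the membrane-bound Cx3cl1 (164 ± 53.7 CPM and 11.8). Of 16 adhesion genes 2 rose (4 adjusted over the list alone); their median was -0.24 while the mean of 0.03 and the test pointed up (camera adjusted p = 0.452, and adjusted p = 0.725 with an estimated correlation). Cell cycle genes had 1 fall of 22, Aurkb (-2.88), and 19 adjusted over the list alone (median -2.31, camera adjusted p = 5.75e-17, and adjusted p = 0.344 with an estimated correlation).

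Vsir in endothelial cells was 25.9 ± 9.47 CPM and 33.2 (-0.26, SE 0.45, edgeR adjusted p = 0.791). T and NK transcripts had 1 rise of 13, Lat, at least 15.2-fold (12 adjusted over the list alone, median 4.13, or 3.81 with bounds, camera adjusted p = 4.29e-12, and adjusted p = 0.363 with an estimated correlation). Trbc2 read 46.2, 61.7 and 18.3 CPM against 0.562 and Hbb-bs 1214, 1167 and 117 against 77.4. In all 237 of 13141 genes passed the edgeR test, 182 higher and 55 lower. The share of rises, 76.8%, was 49.6% without replicate 3 and lay between 58.85% and 100% in the other settings. The isograft cells came mostly from cluster 7 and the allograft cells from cluster 3. Without replicate 2 the count was 18 and without replicate 3 it was 3781, and 23 of 30 named genes that passed lost their call without replicate 2.

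In neutrophils, short-lived phagocytes of the blood, Cxcl9 was at least 268-fold higher (1367 ± 331 CPM against 0), Cd274 rose to 3941 ± 686 CPM from 442 (3.41, SE 0.75, edgeR adjusted p = 0.0164), and Nlrc5, the regulator of class I genes, to 382 ± 24.5 from 11.9 (5.21, SE 0.76, edgeR adjusted p = 0.00118). The scavenger receptor Cd36 fell (-3.06, SE 0.64, edgeR adjusted p = 0.0124), a call not made by DESeq2. Interferon-gamma response genes had 27 rises of 28 (28 adjusted over the list alone, median 6.37, or 5.52 with bounds, camera adjusted p = 7.3e-73, and adjusted p = 0.332 with an estimated correlation). Type I genes had 23 of 28 (27 adjusted over the list alone, median 3.1, camera adjusted p = 2.66e-37, and adjusted p = 0.338 with an estimated correlation). Class I genes had 14 of 20 (17 adjusted over the list alone, median 3.0, camera adjusted p = 4.51e-23, and adjusted p = 0.338 with an estimated correlation). Class II genes had 5 of 9 (8 adjusted over the list alone, median 2.85, camera adjusted p = 1.71e-08, and adjusted p = 0.48 with an estimated correlation). H2-Eb1 read 1000, 908 and 123 CPM against 28.9. Free RNA from other leukocytes was not tested as a source of class II counts in neutrophils. Among the allografts, replicate 3 was lowest both for H2-Eb1 and for the T cell transcript Trbc2 given below. Vsir was 100 ± 32.3 CPM and 167 (-0.59, SE 0.47, edgeR adjusted p = 0.712). Matrix genes had 3 falls of 17 (1 up and 13 down adjusted over the list alone, median -2.01, camera adjusted p = 9.49e-13, and adjusted p = 0.361 with an estimated correlation), with Tagln (-2.99), Mgp (-3.23) and Mfap5 (-3.13), and the T cell transcript Trbc2 read 212, 41.6 and 4.83 CPM against 0. In all 236 of 5679 genes passed, 200 higher and 36 lower. Isograft neutrophils came mostly from cluster 20 and allograft ones from cluster 16. Without replicate 3 the count was 678.

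In conventional dendritic cells, which prime T cells, interferon-gamma genes were higher and stress genes lower. The fall of stress genes was not particular to this class. The list's median was also negative in macrophages (-1.01), neutrophils (-0.83) and fibroblast-scoring cells (-0.40), and was 0.18 in endothelial cells. With a lone isograft, a difference in handling cannot be told apart from a response to the allograft. Interferon-gamma response genes had 18 rises of 27 (24 up and 1 down adjusted over the list alone, median 3.81, or 3.57 with bounds, camera adjusted p = 1.63e-55, and adjusted p = 0.379 with an estimated correlation), with Iigp1 at least 84.2-fold and Gbp8 at least 23.9-fold higher. Class I genes had 5 of 20 (14 adjusted over the list alone, median 1.38, camera adjusted p = 2.7e-14, and adjusted p = 0.453 with an estimated correlation), while none of 12 class II genes passed (3 down adjusted over the list alone, median -0.44, camera adjusted p = 0.0133, and adjusted p = 0.579 with an estimated correlation). The chemokine Ccl4 fell to 859 ± 385 CPM from 8763 (-3.48, SE 0.39, edgeR adjusted p = 0.00985), Tnf to 69.8 ± 29.5 from 381 (-2.56, SE 0.37, edgeR adjusted p = 0.0246) and the heat shock gene Hspa1a to 345 ± 52.3 from 2565 (-3.02, SE 0.22, edgeR adjusted p = 0.00434). Stress genes had 7 falls of 17 (11 adjusted over the list alone, median -1.47, camera adjusted p = 2.02e-18, and adjusted p = 0.579 with an estimated correlation). Vsir was 61.8 ± 24.3 CPM and 88.3 (-0.66, SE 0.44, edgeR adjusted p = 0.523), and Trbc2 read 61.9, 61.8 and 5.65 CPM against 1.40. In all 124 of 9543 genes passed, 71 higher and 53 lower, with 199, 462 and 1638 when replicates 1, 2 and 3 were left out in turn. The share of rises, 57.3%, was 49.8% without replicate 3 and lay between 50.7% and 63.1% in the other settings.

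In monocytes and T cells no single gene passed over all genes, and no list named here passed with an estimated correlation. The isograft held 32 monocytes and 43 T cells, and edgeR called 0 of 14328 and 0 of 13862 genes. At an unadjusted p under 0.05 it found 1444 and 1647, and DESeq2 called 240 and 106. The median log2 change of all genes was 0.83 and 0.95 with edgeR and -0.82 and -0.92 with DESeq2, so list medians and counts are to be read against that shift. The edgeR fits were therefore repeated, after the data were seen, with libraries scaled to a median change of 0. Medians with bounds were not scaled and scaled medians hold no bounds, so neither carries both corrections. In monocytes the median was 3.66 for interferon-gamma response genes, or 2.71 with bounds (22 of 28 rose adjusted over the list alone, camera adjusted p = 4.26e-58, and adjusted p = 0.175 with an estimated correlation), and scaled it was 2.83, with 19 of 28. It was 2.6 for class II genes, or 1.90 with bounds (8 of 12 adjusted over the list alone, camera adjusted p = 2.21e-13, and adjusted p = 0.358 with an estimated correlation), and scaled 1.75, with 0 of 12. In T cells it was 3.14 for cell cycle genes, or 1.99 with bounds (18 of 22 adjusted over the list alone, camera adjusted p = 3.46e-21, and adjusted p = 0.312 with an estimated correlation), and scaled 2.18, with 4 of 22. The median was 2.55 for cytotoxic genes, or 1.06 with bounds (6 of 21 adjusted over the list alone, camera adjusted p = 3.26e-12, and adjusted p = 0.312 with an estimated correlation), and scaled 1.60, with 3 of 21. It was -1.60 for naive T cell genes (2 of 11 fell adjusted over the list alone, camera adjusted p = 3.32e-08, and adjusted p = 0.432 with an estimated correlation), and scaled -2.55, with 6 of 11. Immediate-early and heat shock genes had medians of -0.34 in monocytes and -1.16 in T cells. Scaled, these were -1.17 and -2.11, with 11 and 14 of 17 lower adjusted over the list alone. Their scaled camera adjusted p was 3.37e-16 and 5.21e-36, and with an estimated correlation 0.194 and 0.558. Vsir was 107 ± 26.1 CPM and 256 in monocytes (-0.91, SE 0.47, edgeR adjusted p = 0.594; 25 isograft counts) and 68.6 ± 4.31 and 123 in T cells (-0.51, SE 0.29, edgeR adjusted p = 0.77; 9 isograft counts). Leaving out replicate 3 gave 956 monocyte genes.

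**Figure D3:**
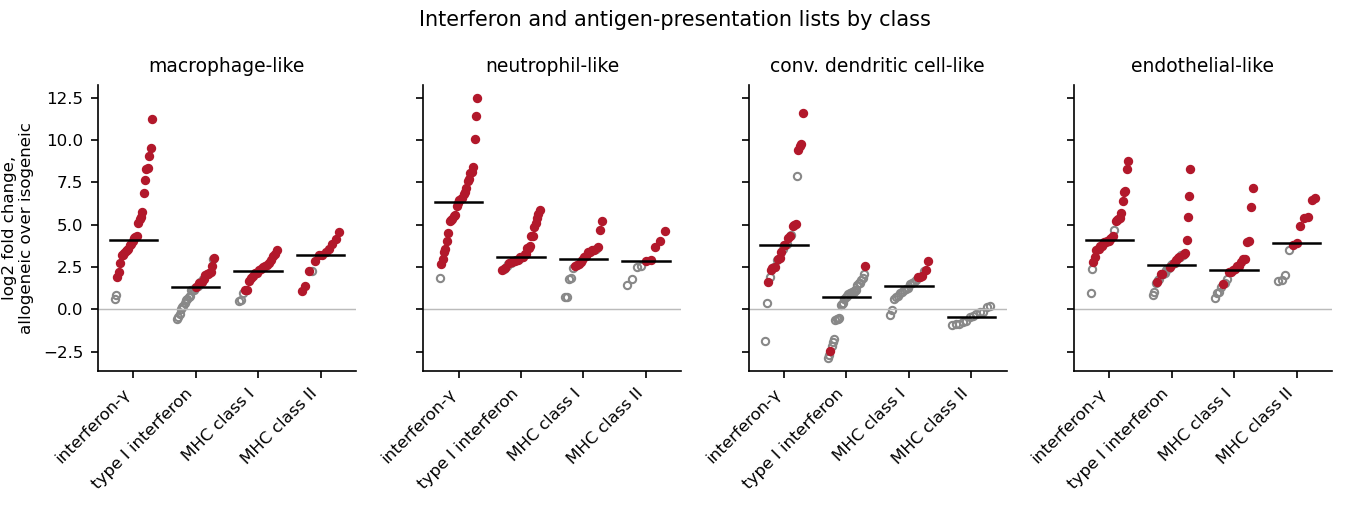
Each point is the log2 fold change, allogeneic over isogeneic, of a member of the interferon and antigen presentation lists in macrophages, neutrophils, conventional dendritic cells and endothelial cells, filled where the edgeR adjusted p was under 0.05, and lines are list medians. Class II genes had medians of 3.24 in macrophages and -0.44 in dendritic cells, and fitted values of genes with few or no isograft counts are not bounds.

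A further question was where Vsir is transcribed in the graft. Over the 4 libraries macrophages held 108 ± 29.3 CPM (SD, n = 4), above endothelial cells (27.7 ± 8.53 CPM; log2 difference 2.36, SE 0.23, edgeR adjusted p = 2.28e-09) and mural cells (22.1 ± 12.4 CPM; 2.85, SE 0.27, edgeR adjusted p = 1.93e-09) in 4 of 4 libraries. It was also higher than in conventional dendritic cells (68.4 ± 23.9 CPM; 0.93, SE 0.23, edgeR adjusted p = 0.00338; 4 of 4) and T cells (82.3 ± 27.6 CPM; 0.84, SE 0.23, edgeR adjusted p = 0.00313; 3 of 4). Monocytes (144 ± 77.2 CPM; -0.098, SE 0.22, edgeR adjusted p = 0.859) and neutrophils (117 ± 42.4 CPM; -0.43, SE 0.23, edgeR adjusted p = 0.126) did not differ past the threshold from macrophages, whose CPM was the higher in 2 of 4 and 3 of 4 libraries. Without replicate 1 the call was lost for T cells (edgeR adjusted p = 0.0532) and dendritic cells (0.0686), without replicate 2 for T cells (0.053), and with no library block for dendritic cells (0.0596). After each cell was thinned to 2000 UMIs, a Vsir UMI was found in 22.8% (18.3 to 28.0), 25.7% (21.6 to 30.3) and 12.98% (9.08 to 18.2) of macrophages of replicates 1, 2 and 3 and in 22.2% (20.6 to 23.9) of isograft macrophages. Unthinned, the shares were 71.4%, 64.2%, 40.7% and 39.9%, at median depths of 13242, 9576.5, 8369 and 4364 UMIs. Too shallow for thinning were 16, 27, 23 and 423 macrophages. As a background for free RNA, isograft fibroblasts, at a median of 9622 UMIs, had 1.16% (0.888 to 1.52), and endothelial cells had 5.10%, 4.62%, 3.16% and 6.93%.

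**Figure D4:**
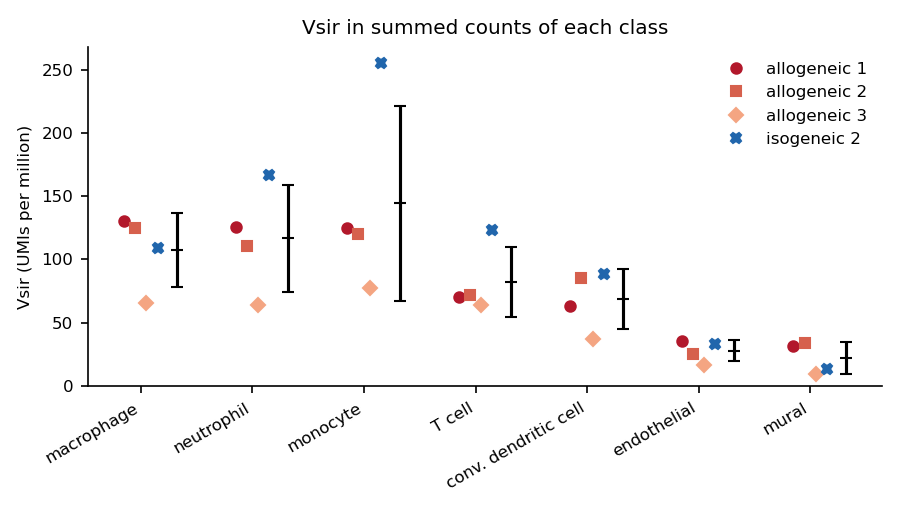
Vsir as CPM in the summed counts of each class, with a point per library and bars for the mean and SD over the 4 libraries. Macrophages averaged 108 CPM and endothelial cells 27.7.

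To ask which genes go with Vsir inside a library, macrophages with a Vsir UMI after thinning (64, 98, 27 and 558 cells in replicates 1, 2 and 3 and the isograft) were set against those without (217, 283, 181 and 1956); a cell without a UMI is not shown to lack Vsir. Cxcl9 was lower in cells with a Vsir UMI by a log2 difference of -0.37 (SE 0.085, edgeR adjusted p = 0.00557), Cxcl11 by one of -0.72 (SE 0.15, edgeR adjusted p = 0.00141) and the interferon-stimulated Rsad2 by one of -0.62 (SE 0.15, edgeR adjusted p = 0.0135), each in 4 of 4 libraries. Some of these differences carry little weight. In the isograft Cxcl9 read 0 against 3.58 CPM and Cxcl11 5.38 against 12.3, and Rsad2 in replicate 2 read 102 against 110. Ccl7 was lower (-0.55, SE 0.086, edgeR adjusted p = 3.31e-07) in 3 of 4. H2-Ab1 (0.069, SE 0.073, edgeR adjusted p = 1.00), Ciita (0.31, SE 0.24, 0.983), Il1b (0.40, SE 0.13, 0.278) and Tnf (-0.23, SE 0.13, 0.972) did not pass. Il1b passed as higher without replicate 2 (0.63, edgeR adjusted p = 0.0194), and turned to -0.57 without the isograft and to -0.28 and -0.42 at 1000 and 4000 UMIs. Of 16 chemokines 3 were lower (4 adjusted over the list alone, median -0.12, camera adjusted p = 5.57e-07, and adjusted p = 0.492 with an estimated correlation), and of 9 class II genes none passed (median 0.069, camera adjusted p = 0.0477, and adjusted p = 0.492 with an estimated correlation). For 13 inflammatory genes the median was 0.042 (camera adjusted p = 0.809), and none passed, or 2 higher adjusted over the list alone. Haemoglobin transcripts moved with this split: Hbb-bs was lower (-2.25, SE 0.19, edgeR adjusted p = 2.8e-29), at 51.02 CPM against 1092 in replicate 2, as was the cell cycle gene Ube2c (-1.09, SE 0.28, edgeR adjusted p = 0.0259). Of 9 cell cycle genes 3 were lower, Ube2c, Birc5 (-0.78) and Stmn1 (-0.59) (7 adjusted over the list alone, median -0.75, camera adjusted p = 9.81e-07, and adjusted p = 0.509 with an estimated correlation). Other lower genes known from dividing cells, picked out after their values were seen, were Dut, Hmgb2, Pclaf and the histone genes H2ac8 and H2ac24. Without replicate 2 Hbb-bs was at -0.89 (edgeR adjusted p = 0.111), and without replicate 1 Ube2c was at -1.08 (edgeR adjusted p = 0.27). The neutrophil transcript S100a8 was higher (1.24, SE 0.20, edgeR adjusted p = 3.15e-07), in 2 of 4 libraries, at 153 CPM against 56.0 in the isograft. At 1000 UMIs Hbb-bs turned to 0.63 and S100a8 to -0.48, and with no thinning Ube2c turned to 0.17 and S100a8 to -0.064. In all 19 of 4830 genes passed, 4 higher and 15 lower, and 255 had an unadjusted p under 0.05 where chance gives 241.5. The count was 8 without the dividing cluster, a setting chosen after the data were seen, and 3 without the isograft. No gene passed edgeR when cells were matched by cluster (89 at an unadjusted p under 0.05, where chance gives 120) or when thinned to 1000 UMIs (136, where chance gives 165), or with DESeq2.

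Whether the allogeneic effect differed between macrophages and endothelial cells was tested as an interaction, which 112 of 13955 genes passed. The difference, the log2 change in macrophages minus that in endothelial cells, was positive for 50 and negative for 62, and 67 of 111 had changes of opposite sign in the 2 classes. Nos2 had the larger effect in macrophages (difference 7.37, SE 0.45, edgeR adjusted p = 0.00334), as did Cxcl9 (2.46, SE 0.37, edgeR adjusted p = 0.0449), and Cxcl10 the larger one in endothelial cells (-3.60, SE 0.57, edgeR adjusted p = 0.0477). For Cxcl9 the isograft level was lower in macrophages, while its mean CPM in the allografts was higher in endothelial cells. Differences for H2-Ab1 (-1.50, edgeR adjusted p = 0.103), Ciita (-1.99, 0.178), Cd274 (-1.15, 0.168) and Vsir (0.33, 0.722) did not pass. Without replicate 2 the count was 34, and without replicates 1 and 3 it was 601 and 1478.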

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

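The comparison of macrophages with endothelial cells was planned, and that with fibroblast-scoring cells, the fibroblasts joined with unnamed clusters that scored highest for their markers, was chosen after the cells had been grouped.

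Between macrophages and endothelial cells, 112 genes had an allogeneic effect that differed by the edgeR test of the difference itself, and 67 of 111 such genes had effects of opposite sign. Cxcl9 rose in both classes and by 2.46 more on the log2 scale in macrophages. That larger change rests on a lower isograft level in macrophages. In the allografts the mean Cxcl9 CPM was higher in endothelial cells than in macrophages. Cxcl10 differed by -3.60, with a log2 change of 0.62 in macrophages and 3.99 in endothelial cells. Nos2 differed by 7.37, with 8.31 in macrophages and 0.96 in endothelial cells. The list of type I interferon response genes had a median difference (macrophage minus endothelial log2 change) of -1.47, with 2 of 30 genes passing as negative. For the cell cycle list it was 2.06, with 1 of 22 genes passing as positive, and the list's median change was -0.47 in macrophages and -2.31 in endothelial cells. Without replicates 1, 2 and 3 in turn, 601, 34 and 1478 genes differed.

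Between macrophages and fibroblast-scoring cells the effect differed for 302 genes, of which 15.2% had a positive difference (macrophage minus fibroblast-scoring log2 change). Without replicate 1 the count was 204, and without replicate 3 it was 3351, of which 29.9% were positive.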

How the results depend on the processing

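The seeds 2 to 6, the scaling of monocytes and T cells to a median change of 0, the settings without the cycling or mixed cluster and all fits of fibroblast-scoring cells were chosen after the data were seen. Each result was counted once per alternative, and the alternatives share cells, so the counts are not independent. For single genes in macrophages 985 were the same, 84 weaker, 16 stronger and 22 reversed. In that order, macrophage lists gave 150, 20, 8 and 8, shares 134, 4, 12 and 6, and the Vsir UMI comparison 148, 65, 2 and 22. Of the 62 macrophage genes counted, 55 passed in the main fit. Those outside the fixed genes were picked for passing or for large changes in these data, so their unchanged direction says little. All 22 reversals in macrophages were of Vsir, Il1b, Cd80 and Cxcl10, fixed genes that did not pass. The causes of the changes below were not tested.

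Macrophage genes past the threshold numbered 1449 with no filter, 1358 at a mitochondrial limit of 10%, 271 at resolution 2, 1256, 2071, 1700, 1168 and 1171 with seeds 2 to 6 (747 with seed 1, the lowest), 315 with equal numbers of macrophages thinned to 2000 UMIs, and 117 to 4788 when replicates were left out. DESeq2 called 872, 73.1% of them higher against 62.4% in the main fit. That share was 47.35% without replicate 3 and 49.14% with no filter. In the other settings it lay between 50.02% (seed 3) and 89.74% (without replicate 2), so a majority of rises did not hold throughout. Over seeds, the macrophages of allogeneic replicate 1 numbered 297 to 1251. Resolution 0.5 was not run for macrophage genes, as libraries held 1, 1 and 69 macrophages. Counts in other classes with DESeq2, with no filter and over left-out replicates were 240, 27 and 0 to 956 for monocytes, 187, 875 and 199 to 1638 for dendritic cells, 106, 7 and 0 to 99 for T cells, 713, 746 and 18 to 3781 for endothelial cells and 856, 1108 and 427 to 2990 for fibroblast-scoring cells. Neutrophil genes ranged from 202 to 678 over left-out replicates, and DESeq2 called 97.0% of them higher against 84.8%. With an estimated correlation 0 lists passed. Classes with a changed share were 4 with doublets kept, 4 with TMM and 0 to 9 over left-out replicates. Vsir was higher in macrophages than in 2 to 4 classes over left-out replicates. The Vsir UMI comparison gave 0 genes at 1000 UMIs, with DESeq2 and matched by cluster, 44 at 4000 UMIs, 8 with no thinning, 3 in allogeneic libraries only, 11 with no filter, 8 without the cycling cluster and 3 to 16 over left-out libraries. The interaction with endothelial cells gave 478 with no filter and 34 to 1478 over left-out replicates, and that with fibroblast-scoring cells 1338 and 204 to 3351.

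These log2 values changed sign. Vsir in macrophages became 0.018 with DESeq2, 0.0075 with doublets kept, 0.028, 0.0085, 0.0080 and 0.027 with seeds 2 to 5, 0.0060 with monocytes joined and -0.13 to 0.23 over left-out replicates. Il1b became 0.51 with doublets kept, 0.76 at the mitochondrial limit of 10%, 0.30 at resolution 2, 0.27, 0.94 and 0.66 with seeds 2 to 4 and 2.19 with monocytes joined, and was -1.14 to -0.76 over left-out replicates. Cd80 became 0.14, 0.35, 0.0096, 0.39 (seed 3), 0.22 (seed 4) and 0.96 in the same settings, and Cxcl10 ranged from -0.40 to 0.98 over left-out replicates. With monocytes joined the list medians became 0.0060 for VISTA partners, -0.037 for complement, -0.26 for haemoglobin and 0.38 for neutrophil transcripts. Over left-out replicates they ranged from -0.13 to 0.22 for VISTA partners, -0.12 to 0.073 for lysosome, -1.58 to 1.84 for haemoglobin and -0.64 to 0.11 for neutrophil transcripts. The share of dendritic cells became -0.50 with TMM, and that of endothelial cells 0.058 with doublets kept, 0.028 at the mitochondrial limit of 10% and -0.17 to 0.16 over left-out replicates, while neutrophils went from -1.32 to 0.16. Vsir against monocytes ranged from -0.23 to 0.083. In macrophages with a Vsir UMI, Il1b became -0.28 at 1000 UMIs, -0.42 at 4000, -0.27 with no thinning, -0.57 in allogeneic libraries only, -0.21 with DESeq2 and -0.57 to 0.63 over left-out libraries. Cxcl10 became 0.11 matched by cluster, Arg1 0.046 at 4000 UMIs and 0.0089 with no thinning, and Nos2 -0.42 at 4000 UMIs, -0.0015 with no thinning and -0.058 to 0.44 over left-out libraries. H2-Ab1 became -0.088 at 1000 UMIs, -0.11 with no thinning, -0.059 with no filter and -0.032 matched by cluster, and H2-K1 -0.066 with no filter. With no thinning Ube2c became 0.17 (-1.45 to -1.07 over left-out libraries) and Birc5 0.11 (-0.92 to -0.44), and S100a8 -0.064, or -0.48 at 1000 UMIs, where Hbb-bs became 0.63 (-4.07 to -0.89 over left-out libraries).

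No paired analysis was possible because the groups share only replicate number 2. The isograft held 32 monocytes, 43 T cells and 10 NK cells, and its neutrophils had a median of 1095 UMIs, which limits what these classes can show.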

Other observations

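Of the tests in this part, those of free RNA and of handling stress, and the comparison in fibroblast-scoring cells, were chosen after the result was seen, while the tests of genotype and of shared paralog reads were set beforehand.

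Fibroblast-scoring cells, drawn mostly from cluster 1 in the isograft and cluster 5 in the allografts, carried the interferon-gamma genes seen in other classes. Only 1 and 7 cells of replicates 1 and 2 were named fibroblasts, against 481 in replicate 3 and 4563 in the isograft. The comparison thus sets allograft cells largely from unnamed clusters against isograft cells mostly named fibroblasts. Cxcl9 rose to 4083 ± 750 CPM (SD, n = 3) from 0.785 (log2 12.31, SE 0.62, edgeR adjusted p = 0.000762), Cd274 by 5.88 (SE 0.48, edgeR adjusted p = 0.00214), the class II gene H2-Ab1 by 6.17 (SE 0.61, edgeR adjusted p = 0.00415) and the complement genes C2 by 4.27 and C4b by 4.61. Interferon-gamma response genes had 25 rises of 28 (28 adjusted over the list alone, median 5.33, camera adjusted p = 2.12e-136, and adjusted p = 0.0503 with an estimated correlation), class I genes 18 of 20 (18 adjusted over the list alone, median 2.68, camera adjusted p = 2.4e-56, and adjusted p = 0.0503 with an estimated correlation) and complement genes 5 of 12 (5 adjusted over the list alone, median 1.06, camera adjusted p = 6.19e-09, and adjusted p = 0.159 with an estimated correlation). Matrix genes had 4 falls of 22 (8 adjusted over the list alone, median -0.94, camera adjusted p = 8.71e-12, and adjusted p = 0.305 with an estimated correlation), among them Tagln (-2.88). T and NK transcripts had 10 rises of 13 (12 adjusted over the list alone, median 5.69, camera adjusted p = 6.66e-38, and adjusted p = 0.159 with an estimated correlation), and Gzmb, the granule protease of killer cells, read 101, 124 and 116 CPM against 0.102 on 6 isograft counts. Haemoglobin transcripts had 3 falls of 4, with Hbb-bs at -3.73. Vsir was 16.3 ± 7.44 CPM and 7.64 (1.00, SE 0.56, edgeR adjusted p = 0.483). In all 344 of 15682 genes passed, 286 higher and 58 lower, and without replicates 1 and 3 the counts were 628 and 2990. The share of rises, 83.1%, was 79.9% without replicate 1, 49.2% without replicate 3 and 64.1% with no filter.

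MHC class II transcripts were higher in endothelial cells of the allografts, where free RNA from class II-rich leukocytes is a possible explanation. One source would keep Ciita and H2-Ab1 in one ratio, but their ratio in endothelial cells was at least 1.77 times that in the leukocytes of the same library (1.57 to 2.01 in replicate 1, and 2.28 and 1.89 in replicates 2 and 3). Scaled by the ratio in leukocytes, H2-Ea counts accounted for at most 52.4% of endothelial H2-Ab1 (46.9 to 58.4 in replicate 1, and 33.8% and 5.03% in replicates 2 and 3). Both argue against free RNA as the whole source, and a part from it stays open. A response of the vessel lining to the allogeneic recipient is a hypothesis that these libraries leave untested.

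Trim12a had 0 counts in endothelial, mural and fibroblast-scoring cells of the isograft, and was the only gene of its kind with at least 10 CPM there in all 3 allografts. Reads shared with its copy Trim12c might produce this. The sum of both in endothelial cells was at least 4.95 times that of the isograft (139, 163 and 268 CPM against 28.1). That argues against a mere shift of reads between the copies at an unchanged total. Trim12c itself was also higher there, at 52.1, 59.7 and 83.9 CPM against 28.1. The sum therefore cannot decide whether Trim12a took in reads of a raised Trim12c. Graft and recipient of an allograft differ in genotype by design, so the open question is whether Trim12a reflects that difference. It was addressed by counting genes nearly absent from graft-resident cells of the allografts and, for comparison, from their macrophages. Both counts were 0 of 6237 genes, which meets the outcome set beforehand as counting against genotype as the explanation. A rule that finds 0 either way has no power, so no conclusion is drawn from it. In the allografts Trim12a read 0.491, 1.24 and 3.29 CPM in macrophages and 1.06, 2.86 and 2.42 in T cells against 86.8, 103 and 184 in endothelial cells. Either the genotype of the graft cells or a response of graft-resident cells could give such a split, so both stay open, as does sharing of reads with Trim12c.

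Ifnb1, the gene of interferon beta, read 2.70 and 1.99 CPM in macrophages of allogeneic replicates 1 and 2, 228 in replicate 3 and 229 in the isograft. Free RNA gives all classes a like level, but endothelial cells of replicate 3 held 1.92% of the macrophage level (0.953 to 3.47), which argues against it as the whole source. A part from it stays open, since fibroblast-scoring cells of replicate 3 read 35.6 CPM, and T and NK cells of the isograft 96.0 and 697 CPM on 7 and 27 counts. Handling stress shared by replicate 3 and the isograft stays open. The dissociation stress list was higher in replicate 3 than in replicates 1 and 2 in 4 of 6 classes. Median log2 differences were 0.31 in macrophages, 0.17 in monocytes, 0.86 in neutrophils, -0.091 in dendritic cells, 0.45 in T cells and -0.15 in endothelial cells. This meets the outcome written for handling stress, a higher list in most of the 6 classes. The count is near what chance gives, and the test leaves out the isograft, so no conclusion is drawn from it. In the comparison of the groups, the list was higher in the isograft in macrophages, neutrophils and dendritic cells, and lower in endothelial cells. No biological explanation was tested, since replicate 3 shares its group with replicates 1 and 2.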
